A study of Mus musculus with 41 samples.

How the data were processed

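Liver poly(A) RNA of 41 mice was measured, 23 under repeated 8 h advances of the light cycle (ADV) and 18 under a fixed cycle (LD). Each library took its group from its treatment label and was matched to its data column by its title. Per the labels' protocols, libraries were made with a stranded mRNA kit and read as paired ends. Per the submitters' processing notes, bcl2fastq, STAR 2.7.2 and HOMER 4.11 were used with the mm10 genome. The role of each tool and whether counting used strand are not given in the sources used here. The first table holds estimated counts per transcript, deposited without scaling per the file headers, in steps of 0.5. The values were rounded to whole numbers before the count tests. The second table holds FPKM values, which the authors deposited beside the counts. They equal counts divided by the total in the file header and by transcript length, checked on all values of at least 20 counts. FPKM served only for alternatives, as log2(FPKM + 0.1). The tables list 55421 transcripts, 1 per gene model, with mm10 coordinates and exon lengths in bases. Another 117 rows repeat a symbol already present and were kept, the bare symbol going to the row with most reads. The rows sum to between 95.5 and 96.6% of the totals in the file headers.

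Genes were filtered with filterByExpr by group, which left 12949, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood fit, intercept and group) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05 over all tested genes. A standard error is the absolute log2 fold change divided by the square root of the F statistic. CPM use TMM-scaled library sizes, and log2 CPM a prior count of 2. The median log2 difference of all genes between groups was under 0.01 in size with each scaling (-0.0042 with TMM). Replicates are separate mice. The most alike pair of libraries, ADV replicates 13 and 16, differed by a chi-square of 23.0 per degree of freedom, far above sampling noise, so no library was counted as a repeat.

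Before the data were examined, 31 gene lists (496 genes) were fixed: clock, lipid synthesis, storage and oxidation, cholesterol and bile acid synthesis, gluconeogenesis, xenobiotic metabolism, male- and female-biased genes, fibrosis, acute phase, inflammation, antigen presentation, interferon, cell cycle, p53, unfolded protein response, heat shock, NRF2, immediate-early genes, hepatocyte zones and markers of other cell types. The 30 lists with at least 3 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01), beside camera with the correlation estimated per list and fry. Genes named in the text are the 12 largest increases and 12 largest decreases among genes past the threshold with a mean of at least 1 CPM in a group and a standard symbol. They are joined by up to 4 passing members per list with the largest change, or else the 1 or 2 with the smallest p, by Arntl, Nr1d1, Dbp and Per2 always, and by the genes of the spread test with the 10 largest and 5 smallest SD ratios, which took all 14. Some genes that this rule names are not reported here.

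Spread between mice was tested with limma on absolute deviations of log2 CPM from the group mean, with robust and trended variance. Whole-profile dispersion used betadisper in vegan 2.7.1 with 99999 permutations. Correlations across mice used 100000 permutations, two-sided, or all orders for fewer than 10 mice, and list scores were means of standardised log2 CPM after centring each group. Scripts were tested on simulated data drawn from the real genes. For ADV against LD over 12949 genes, the expression test recovered 34, 78, 96 and 96% of 50 genes each changed by 1.25, 1.5, 2 and 4-fold, and 4.40% of its calls were unchanged genes. The spread test recovered 0, 18, 56 and 94% of 50 genes each at SD ratios of 1.5, 2, 3 and 4. Camera with the preset correlation called 27.5% of lists without any change, so its calls are given beside the other tests.

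A clock phase was fitted to each mouse for the closing section, from log2 CPM of 13 clock genes scaled to their range over all mice and approximate peak times taken from background knowledge and set after the expression values had been seen. Simulated phases were recovered with a median error of 0.39 h. The simulation used the same peak times as the fit, equal amplitudes for all genes and phases drawn evenly over the day. It does not cover error from wrong peak times or unequal amplitudes in these mice. Alternatives planned before the data were examined were other scalings, filters and tests (DESeq2 1.42.0, voom with quality weights, FPKM with limma), the replicate number as a block, clock components and surrogate variables (sva 3.50.0) as covariates, a fold of 1.5 as null, each mouse left out in turn, and other forms of each list, spread and correlation test. A robust fit, the mitochondrial share as a covariate or regressed out, and the fit without the 3 libraries of largest mitochondrial share were added after seeing the data. Library totals of 13307459 to 24476787 put the precision limit at the spread between mice (biological coefficient of variation 0.274) except for genes near 1 CPM.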

Results

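Liver poly(A) RNA was sequenced from 41 individually housed male C57BL/6J mice, a common inbred laboratory strain, kept with running wheels. The mice called ADV (n = 23) lived for 47 weeks under a light cycle that was moved 8 h earlier every 4 days, a model of chronic jet lag. The mice called LD (n = 18) stayed under a fixed cycle of 12 h light and 12 h dark. Livers were collected between 9.5 and 18 h clock time, and the labels give no hour for single mice. The series title asks how individual mice differ in fatty liver disease under circadian misalignment. Total counts per library ran from 13307459 to 24476787, with means of 19280573 ± 2428584 in ADV and 19276412 ± 2794505 in LD (SD). Mitochondrial transcripts took 7.40 ± 1.83% of counts in ADV and 7.91 ± 2.51% in LD (difference -0.51 percentage points, two-sided permutation p = 0.467). One library, LD replicate 13, stood apart, with the lowest total, a mitochondrial share of 15.7% and the lowest scaling factor, 0.516. Another, ADV replicate 1, held reads of pancreas genes, as given with the tissue markers.

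The first comparison asks which liver transcripts differed after long-term repeated advances. Genes of the circadian clock were among those with the largest differences. Dbp, a transcription factor driven by the clock, stood at 2.83 ± 1.53 CPM in ADV against 39.3 ± 39.8 CPM in LD (mean ± SD, n = 23 and 18). Nr1d1 and Nr1d2, which encode the REV-ERB repressors, fell from 43.3 ± 22.6 to 4.85 ± 4.90 CPM and from 71.1 ± 34.9 to 20.7 ± 5.48 CPM. In the opposite direction, the repressor gene Cry1 rose from 9.32 ± 5.28 to 27.2 ± 9.96 CPM. Of the 23 ADV mice, 22 lay above the LD median for Cry1, while none lay above it for Dbp, Nr1d1 or Nr1d2.

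Of the 19 clock genes fixed as a list before the data were examined, 2 rose, 5 fell and 12 did not pass the test over all genes. Adjusted over the list alone, 3 rose and 6 fell. The log2 fold changes of ADV over LD were -3.80 ± 0.51 for Dbp (SE, adjusted p = 5.2e-06), -3.16 ± 0.33 for Nr1d1 (adjusted p = 1.4e-08), -1.78 ± 0.18 for Nr1d2 (adjusted p = 1.3e-08) and 1.54 ± 0.23 for Cry1 (adjusted p = 5.9e-05). The repressor genes Bhlhe41 and Ciart also fell, by 2.61 and 2.31 on the log2 scale (adjusted p = 5.8e-05 and 0.00975). The Ciart call ended with voom, FPKM, surrogate variables and either clock component as a covariate, its value turning to 1.04 with the clock component not centred by group, and the Dbp call ended with voom (-1.99). Arntl, which encodes the activator BMAL1, had a log2 fold change of 0.81 ± 0.32 (adjusted p = 0.168), and Per2 one of 0.40 ± 0.30 (adjusted p = 0.538); neither passed. The list as a whole had no single direction (camera adjusted p = 0.971; with an estimated correlation, adjusted p = 0.980), whereas fry's test for change in either direction gave adjusted p = 1.2e-05, the only list of 30 to pass it. On mm10, Dbp lies on chromosome 7 from 45705088 to 45710203, Nr1d1 on chromosome 11 from 98767932 to 98775333, Nr1d2 on chromosome 14 from 18204054 to 18239127 and Cry1 on chromosome 10 from 85131700 to 85185064. The values are sums over the exons of 1 transcript per gene.

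**Figure D1:**
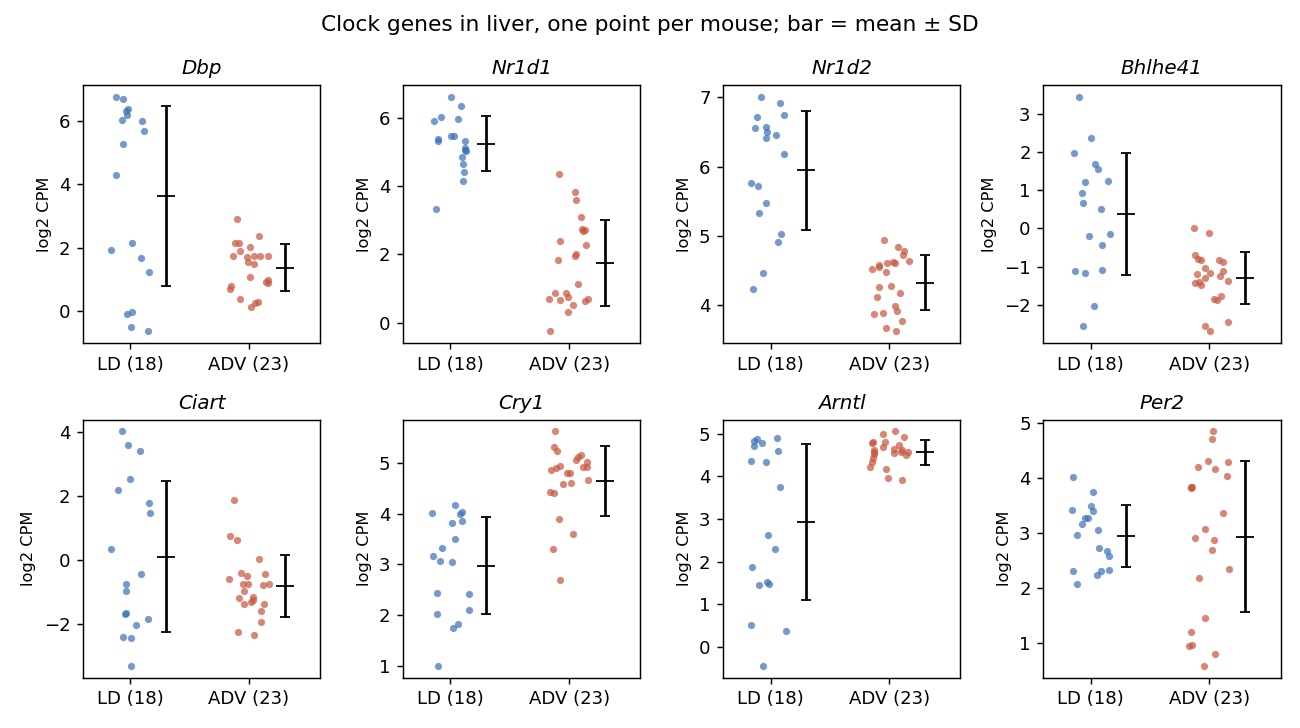
Each panel shows log2 CPM of 1 clock gene on the vertical axis, with 1 point per mouse for 18 LD and 23 ADV mice and a bar for mean ± SD. Dbp, Nr1d1, Nr1d2, Bhlhe41 and Ciart are lower and Cry1 higher in ADV, Arntl is spread widely in LD (SD 1.83) and tightly in ADV (SD 0.29), and Per2 has an SD of 1.38 in ADV and 0.57 in LD.

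Over all 12949 genes tested, 218 were higher and 178 lower in ADV at an adjusted p under 0.05 (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and 25 of the former and 23 of the latter changed more than 2-fold. Besides Cry1, the 12 largest increases held Lingo4 (log2 fold change 1.91 ± 0.24 SE) and Cdkn1a, the cell cycle inhibitor, at 1.68 ± 0.42. Cdkn1a stood at 11.5 ± 9.60 CPM in ADV and 3.55 ± 3.64 CPM in LD and was the 1 member of 12 p53 target and senescence genes to pass. The detoxification gene Cyp2b10 rose by 1.48 ± 0.30, the kinase gene Pdk4, which restrains pyruvate oxidation, by 1.48 ± 0.30, and the hormone gene Fgf21 by 1.39 ± 0.39. Nat8f7 (1.82), Slc22a26 (1.67), Rad51b (1.56), Slc34a2 (1.53) and Npnt (1.49) were also in this group, with adjusted p between 0.00194 and 0.0438. The Rad51b call ended without any 1 of 21 mice, and the Nat8f7 call without LD replicate 14 (1.74). Both also ended without the 3 libraries of largest mitochondrial share, a check chosen after seeing the data. The 12 largest decreases held, besides the 5 clock genes, Rgs16 (-1.94), the steroid dehydrogenase gene Hsd3b5 (-1.73), Clec2h (-1.49), Gnat2 (-1.31), Hectd2os (-1.25) and the immunoglobulin segment Igkv12-46 (-2.32). The Igkv12-46 value came from 1 animal: without LD replicate 14 it was 0.45 (adjusted p = 0.658). The Rgs16 call ended without LD replicate 18 (-1.66). Nat8f7, Slc22a26, Cyp2b10, Hsd3b5, Clec2h, Igkv12-46 and Acot1 have close sequence relatives, and Hectd2os is an antisense gene whose reads are uncertain because strand use in counting is not given in the sources used here.

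**Figure D2:**
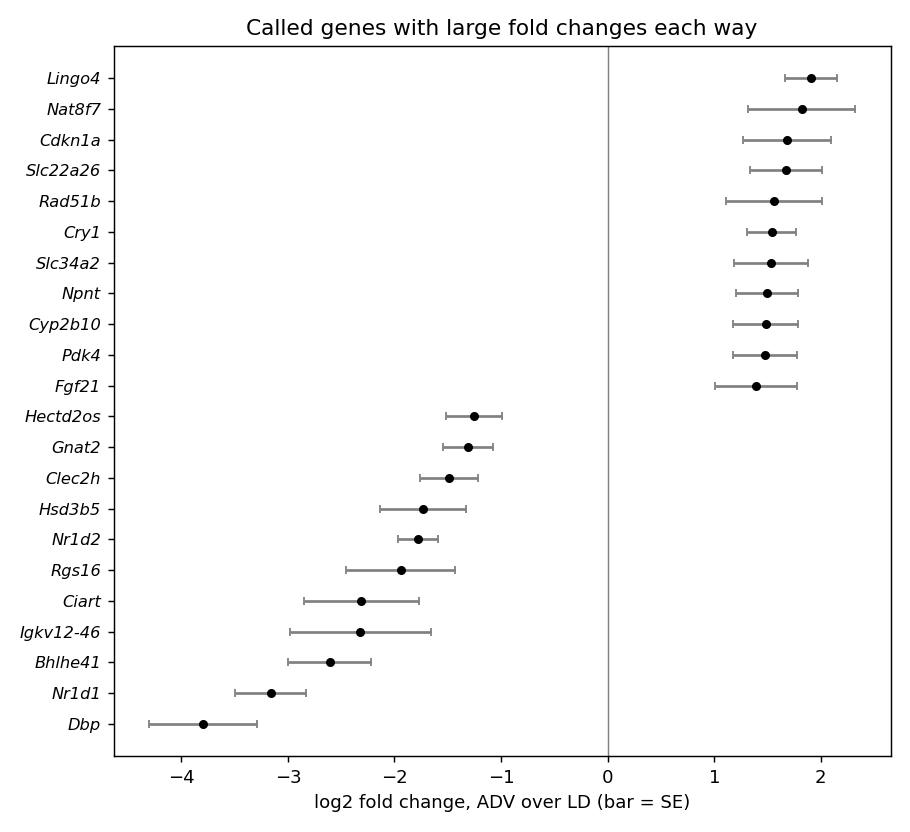
The horizontal axis gives the log2 fold change of ADV over LD with its SE for those of the 12 largest increases and 12 largest decreases that are reported here, among genes that passed the test. Values run from -3.80 for Dbp to 1.91 for Lingo4, and the Igkv12-46 value rests on 1 LD mouse.

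Some genes of fatty acid use were higher in ADV. Of 20 fatty acid oxidation and PPARA target genes, 6 rose, none fell and 14 did not pass (9 rose adjusted over the list alone). Pdk4 went from 12.5 ± 8.47 to 34.9 ± 23.4 CPM and Fgf21 from 0.89 ± 0.76 to 2.38 ± 2.25 CPM. The acyl-CoA thioesterase gene Acot1 rose from 25.8 ± 13.8 to 51.1 ± 24.9 CPM and the peroxisomal oxidation gene Ehhadh from 320.4 ± 78.7 to 467 ± 222 CPM. The list was called higher by camera (adjusted p = 3.5e-08), not with an estimated correlation (adjusted p = 0.362), and by fry (adjusted p = 0.0372). The Fgf21 call ended without any 1 of 8 mice and the Ehhadh call without any 1 of 18. Both also ended without the 3 libraries of largest mitochondrial share, a check chosen after seeing the data.

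Few genes of lipid storage and synthesis passed the test. Of 17 lipid droplet and PPARG target genes, 2 rose and 15 did not pass, with 5 higher adjusted over the list alone. Plin5 and Plin4, which coat lipid droplets, rose from 48.3 ± 12.4 to 88.8 ± 40.1 CPM and from 7.88 ± 4.44 to 15.7 ± 6.88 CPM. Of 19 fatty acid synthesis and lipogenesis genes, 1 rose, the acyltransferase gene Agpat2 of triglyceride synthesis (log2 fold change 0.44 ± 0.08, adjusted p = 0.000733, 22 of 23 ADV mice above the LD median), and 18 did not pass, with 5 higher adjusted over the list alone. Camera called both lists higher (adjusted p = 7.6e-05 and 0.000362). With an estimated correlation neither held (adjusted p = 0.362 and 0.610), nor by fry (adjusted p = 0.0625 and 0.214). Of 20 cholesterol synthesis genes, the sterol carrier gene Stard4 fell (-0.44 ± 0.10, adjusted p = 0.0105) and 19 did not pass, with 4 lower adjusted over the list alone; the list was called lower at adjusted p = 0.0253, and with an estimated correlation adjusted p = 0.795. That call ended without any 1 of 12 mice.

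Some chaperone and stress genes of the endoplasmic reticulum were lower in ADV. Of 19 unfolded protein and integrated stress response genes, 4 fell, none rose and 15 did not pass, with 8 lower adjusted over the list alone. The pseudokinase gene Trib3 fell from 5.68 ± 4.44 to 2.63 ± 1.20 CPM and Sdf2l1 from 43.7 ± 26.9 to 21.7 ± 12.3 CPM. The disulfide isomerase gene Pdia6 fell from 421 ± 264 to 267 ± 67.1 CPM, and Hsp90b1, a chaperone gene, from 1133 ± 572 to 745 ± 193 CPM. The list was called lower by camera (adjusted p = 3.1e-06) and by fry (adjusted p = 0.0372), not with an estimated correlation (adjusted p = 0.362).

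Few genes that differ between male and female liver passed the test in these male mice. Of 15 male-biased genes, 2 fell, Hsd3b5 (247.6 ± 245 to 74.4 ± 69.0 CPM) and the organic anion transporter gene Slco1a1 (443 ± 308 to 248 ± 107 CPM), 13 did not pass, and 9 were lower and 1 higher adjusted over the list alone. All 8 tested female-biased genes had positive log2 fold changes with a median of 0.75, and 1 of them rose, the monooxygenase gene Fmo2 (0.68 ± 0.17, adjusted p = 0.0143). Camera called the male-biased list lower (adjusted p = 9.4e-05) and the female-biased list higher (adjusted p = 0.00434), and both had adjusted p = 0.362 with an estimated correlation and 0.0625 by fry. The Hsd3b5 and Slco1a1 calls ended without the 3 libraries of largest mitochondrial share (LD replicates 13 and 11 and ADV replicate 21), a check chosen after seeing the data, and the Slco1a1 call without any 1 of 18 mice.

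Among the remaining lists, camera called cell cycle genes higher (adjusted p = 0.0117; 0.561 as adjusted p with an estimated correlation), with Aurka (0.66 ± 0.18, a call that ended without any 1 of 10 mice) and Mcm4 (0.41 ± 0.10) risen out of 16. It also called antigen presentation genes higher (adjusted p = 0.0218; 0.752 as adjusted p with an estimated correlation), with H2-K1 (0.23 ± 0.06) risen out of 16, and this list call ended without any 1 of 4 mice and with the mitochondrial share as a covariate (adjusted p = 0.0511). Of 18 xenobiotic metabolism genes, 2 rose, Cyp2b10 and Nr1i3, the gene of the receptor CAR (0.52 ± 0.11, adjusted p = 0.00397), and the list was not called (adjusted p = 0.165). Of 16 bile acid genes, Slco1a1 alone passed (list adjusted p = 0.869). No member passed among genes of gluconeogenesis and insulin response, extracellular matrix and fibrosis, the acute phase, inflammatory cytokines, interferon response, heat shock, NRF2 and oxidative stress or immediate-early response. Their camera adjusted p were 0.0586, 0.0633, 0.0586, 0.334, 0.944, 0.869, 0.123 and 0.191. Fos, an immediate-early gene, had a log2 fold change of -1.50 ± 0.49 that missed the threshold (adjusted p = 0.0847). The fibrosis genes with the smallest p were Loxl1 (-0.51, adjusted p = 0.259) and Mmp2 (-0.25, adjusted p = 0.333).

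Markers of liver cell types showed no member past the threshold over all genes. Camera adjusted p were 0.802 for hepatocyte, 0.869 for pericentral and 0.944 for periportal genes, 0.127 for macrophage and Kupffer cells, 0.832 for lymphocytes, 0.869 for neutrophils, 0.595 for endothelium, 0.307 for cholangiocytes and progenitors, and 0.756 for red blood cells. The macrophage genes Cd68 and Csf1r had log2 fold changes of 0.26 ± 0.11 (adjusted p = 0.223) and 0.27 ± 0.11 (adjusted p = 0.204). Of 11 adipocyte and pancreas markers, 2, Cfd and Adrb3, passed the filter (0.17 and -0.27), too few for a list test. The 5 pancreas markers did not pass it because 1 library held nearly all of their reads: unscaled CPM in ADV replicate 1 ran from 1300.0 for Prss2 to 2192 for Cela2a, with Cpa1, Ctrb1 and Pnlip between them, and the highest value in any other library was 1.97. Without ADV replicate 1, 196 genes were higher and 155 lower, 342 of them shared with the 396, and 13 were more variable in LD, with Npc1 and Mal2 no longer passing. Median and mean log2 fold change differ in sign for the hepatocyte (-0.06 and 0.00088), pericentral (-0.08 and 0.02) and interferon lists (0.02 and -0.0002), and in the heat shock list the median (-0.07) and the test go opposite ways.

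**Figure D3:**
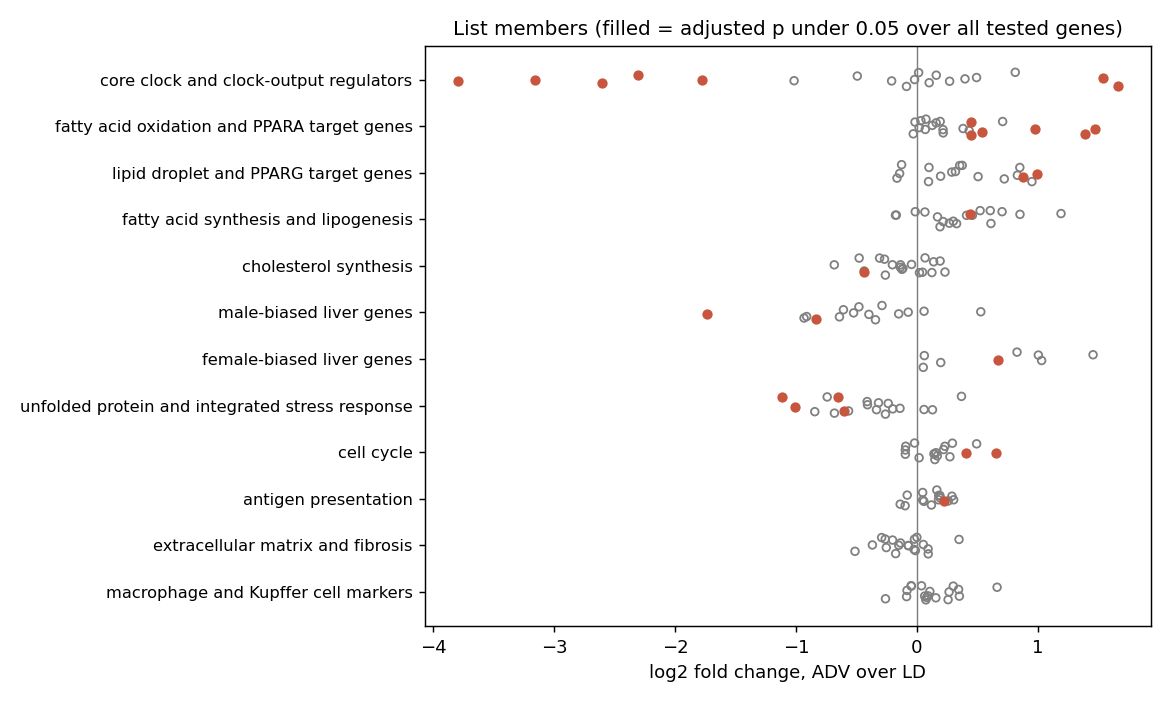
Each point is 1 tested member of a gene list, placed by its log2 fold change of ADV over LD, and filled points passed an adjusted p of 0.05 over all tested genes. An exception is Bub1 in the cell cycle row, which was not tested and is drawn at the value of Bub1b (-0.09). Clock genes reach down to -3.80, 6 fatty acid oxidation genes rose, 4 unfolded protein response genes fell, and no fibrosis or macrophage gene passed.

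In all, camera with its preset correlation of 0.01 called 6 lists higher and 3 lower, none of the 9 held with an estimated correlation, and fry called 1 list in each direction. Of 100 splits of the 41 mice, the real one included, 43 called 9 or more lists. With the clock component, not centred by group and so carrying the group difference, as a covariate, 12 reported calls ended besides Ciart. Mcm4 (0.39 ± 0.11 SE), H2-K1 (0.21 ± 0.06), Aurka (0.62 ± 0.20), Slco1a1 (-0.85 ± 0.27), Nat8f7 (1.78 ± 0.52), Rad51b (1.65 ± 0.53) and Ehhadh (0.45 ± 0.17) moved by less than 0.1 and had larger SEs. Stard4 (-0.31 ± 0.10), Rgs16 (-0.73 ± 0.51), Fgf21 (0.94 ± 0.43), Trib3 (-0.66 ± 0.24) and Igkv12-46 (-0.50 ± 0.79) moved further toward 0. With the component centred by group, Rgs16, Igkv12-46 and Ciart alone of these lost their calls.

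The second comparison asks whether single mice differed more from each other under the advances. Spread between mice was larger in LD, not in ADV, for the genes that passed. Arntl had an SD of log2 CPM of 1.83 in LD and 0.29 in ADV (adjusted p = 8.2e-08), and Dbp one of 2.84 in LD and 0.75 in ADV (adjusted p = 0.000557). The clock repressor gene Ciart, the tubulin gene Tubb2a, the protease gene Pcsk4 and the galectin-like gene Lgalsl also varied more in LD, with SDs 2.44, 3.03, 3.16 and 3.06 times those in ADV. Further genes of this kind were the cholesterol transporter gene Npc1, the manganese transporter gene Slc30a10, Slc5a6, Sgms1, Mal2, Leo1 and Ube2g2, with ratios from 2.54 to 2.87.

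**Figure D4:**
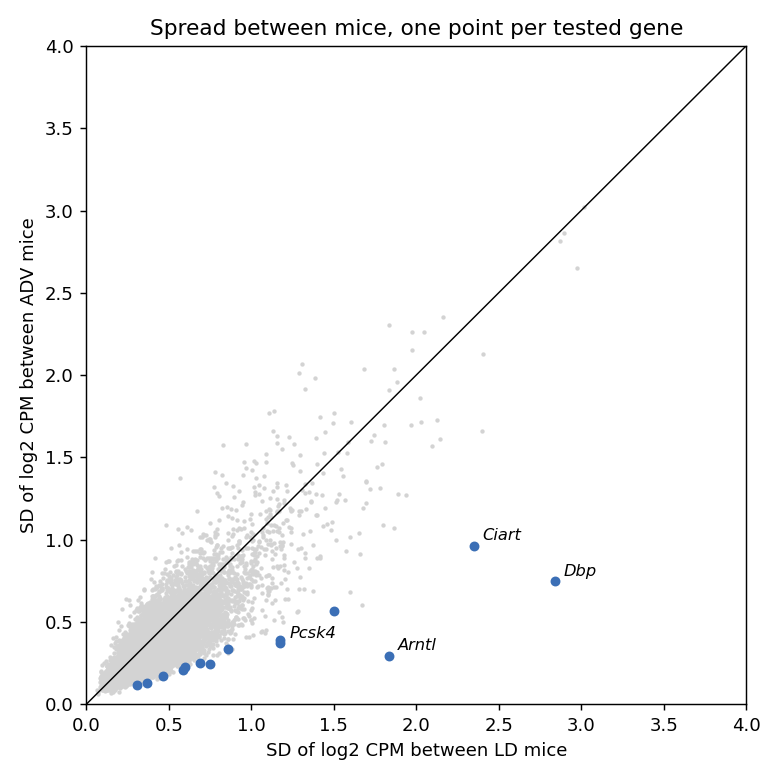
Each point is 1 of 12949 tested genes, with the SD of log2 CPM between 18 LD mice on the horizontal and between 23 ADV mice on the vertical axis, and the line marks equal SDs. The 14 blue genes passed the spread test, all below the line, with Dbp at 2.84 in LD and 0.75 in ADV.

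The spread test (limma on absolute deviations from the group mean) called 14 genes more variable in LD and 0 in ADV, with 1782 genes at an unadjusted p under 0.05; with the mitochondrial share regressed out, a check chosen after seeing the data, 5 genes were more variable in ADV and 50 in LD. Over all tested genes, 26.2% had the larger SD in ADV, and 43.1% without LD replicate 13. Of the 19 clock genes, 3 were more variable in LD by the test. For whole-profile dispersion, distances from the group centroid were 46.6 ± 8.52 in ADV and 52.8 ± 16.2 in LD on the log2 CPM scale, a difference of -6.17 that did not pass (two-sided permutation p = 0.112). It was -1.97 without LD replicate 13, and it passed without ADV replicate 21 (-7.38, p = 0.028). The count of 14 became 39 without ADV replicate 21 and 8 without LD replicate 18.

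Some pairs of clock genes were related across mice. In ADV, Arntl and Dbp were inversely related (Pearson r = -0.69, permutation p = 0.00029, adjusted p = 0.00058; Spearman rho = -0.62, p = 0.00221; n = 23), as were Npas2, a paralogue of the activator gene Clock, and Ciart (r = -0.69, p = 0.00022, adjusted p = 0.00058; rho = -0.61, p = 0.00229). Without the 2 mice farthest from the median these were -0.64 and -0.58. Arntl and Nr1d1 had r = 0.48 in ADV (p = 0.0215, adjusted p = 0.0343; rho = 0.40, p = 0.0602), which rested on 2 mice, since without them r was 0.34 (p = 0.134). Per2 and Nr1d2 had r = -0.13 in ADV (p = 0.564, adjusted p = 0.564; rho = -0.10, p = 0.643) and 0.44 in LD (p = 0.0665, adjusted p = 0.0886; rho = 0.44, p = 0.0721), and without the 2 farthest mice 0.01 and 0.61. Adjustment was over the 8 relations of this family, and the difference between groups for this pair gave adjusted p = 0.0807. By the same permutation test, the differences for Arntl with Nr1d1, Arntl with Dbp and Npas2 with Ciart gave adjusted p = 0.0558, 0.0707 and 0.0558.

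Over all 18 LD mice, as planned, Arntl with Dbp had r = -0.91 and Npas2 with Ciart r = -0.90. Each had permutation p = 1e-05, adjusted p = 4e-05 and rho = -0.89. Without the 2 farthest mice these were -0.91 and -0.89. Arntl with Nr1d1 had r = -0.18 (permutation p = 0.471, adjusted p = 0.538). The LD mice lay on both sides of a gap in Arntl (2.61 to 3.74 log2 CPM) and in Npas2 (0.62 to 1.83). Correlations were therefore also taken within each side, a choice made after seeing the data. A side holds fewer mice and a narrower range of the first gene. Above the gap, Arntl and Dbp had r = -0.84 in 9 mice (exact permutation p = 0.0070, adjusted p = 0.0420 over 6 relations; rho = -0.73, exact p = 0.0311), and -0.48 without the 2 farthest. Below it they had r = -0.44 (n = 9, exact permutation p = 0.232; rho = -0.42, p = 0.270), and 0.03 without the 2 farthest. Npas2 and Ciart had r = -0.70 below the gap (n = 10, permutation p = 0.0252, adjusted p = 0.0757; rho = -0.70, p = 0.0309) and -0.28 above it (n = 8, exact permutation p = 0.512; rho = -0.33, p = 0.428), and -0.58 and 0.16 without the 2 farthest. Arntl and Nr1d1 had r = 0.54 below (n = 9, exact permutation p = 0.134; rho = 0.77, p = 0.0214) and -0.47 above (n = 9, exact permutation p = 0.205; rho = -0.55, p = 0.133), and 0.55 and 0.19 without the 2 farthest.

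**Figure D5:**
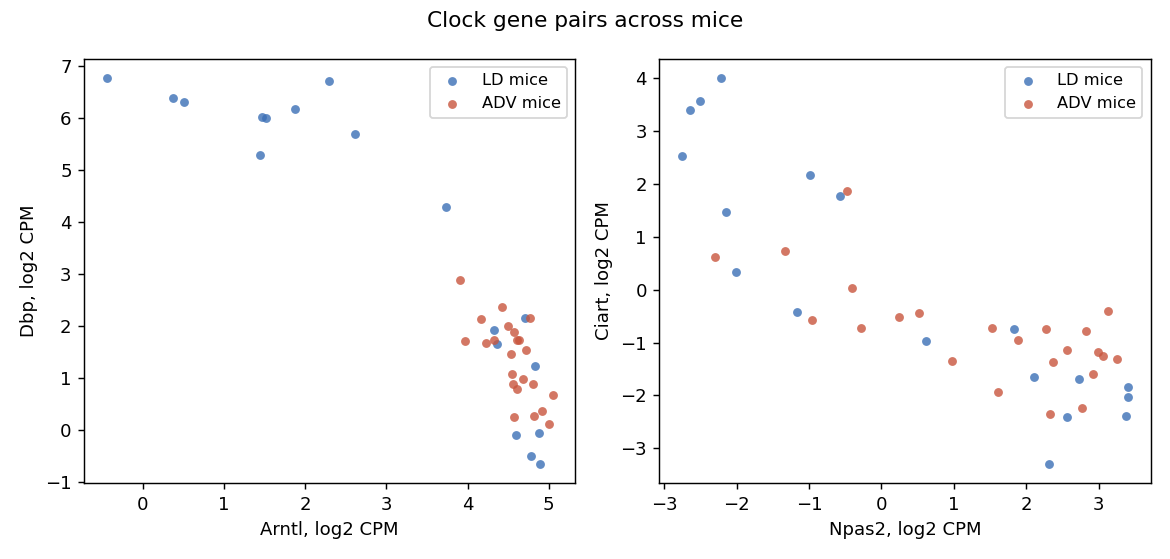
Each point is 1 mouse, with log2 CPM of Arntl and Dbp on the axes of the left panel and of Npas2 and Ciart on those of the right. ADV mice (n = 23) lie at high Arntl and low Dbp, and LD mice (n = 18) lie on both sides of a gap in Arntl between 2.61 and 3.74.

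Scores of gene lists were compared across mice to see whether animals high in one group of genes were high in another. Fibrosis and macrophage scores had r = 0.46 in ADV (permutation p = 0.0280, adjusted p = 0.224; rho = 0.38, p = 0.0754; n = 23) and 0.43 in LD (p = 0.0709, adjusted p = 0.283; rho = 0.45, p = 0.0636; n = 18), and neither passed over the 8 relations of this family. Without the 2 farthest mice the values were 0.30 and 0.41. Fibrosis with lipid droplet scores had r = 0.18 in ADV and -0.34 in LD, macrophage with unfolded protein response scores -0.05 and 0.15, and lipogenesis with lipid droplet scores 0.17 and 0.10. Their Spearman rho were 0.03 and -0.28, -0.09 and 0.13, and 0.21 and 0.11, with permutation p of r from 0.173 to 0.813 and adjusted p from 0.462 to 0.813. None of the 4 differences between groups passed (adjusted p from 0.575 to 0.918).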

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

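The counts of 218 higher and 178 lower genes stayed within 1.5 times of those values under other scalings, a stricter filter, DESeq2, both clock components, the robust fit, and without each mouse in turn (158 to 253 higher, 139 to 214 lower) or the 3 libraries of largest mitochondrial share. Without a filter 110 genes were lower, voom with quality weights gave 334 and 290, FPKM with limma 112 and 114, surrogate variables 992 and 1079, and the mitochondrial share as a covariate, chosen after seeing the data, 353 and 358. The cause was not tested. Against a fold of 1.5 instead of 1, by construction fewer passed, 4 higher (Cry1, Lingo4 and Caln1 among them) and 4 lower (Dbp, Nr1d1, Nr1d2, Bhlhe41). Equal replicate numbers did not mark partners: of 18 numbers in both groups, 8 pairs of deviations correlated over 0.1 and 1 ADV mouse correlated best with its own number. Their order did carry structure. The first principal component of log2 CPM (27.3% of variance) was negative in ADV replicates 1 to 10 and LD replicates 1 to 7, and of mixed sign after them. Heat shock and unfolded protein scores, centred by group, were below 0 in ADV replicates 18 to 23 and LD replicates 14 to 19. An effect of what the replicate number follows, which the labels do not give, is not excluded. With that number as a replicate block, 140 genes were higher and 90 lower, 174 of them shared, and the calls of Dbp (-2.60), Ciart (-1.17), Hsp90b1, Sdf2l1, Pdia6, Cdkn1a, Hsd3b5, Mcm4, H2-K1, Stard4, Ehhadh, Aurka, Fgf21, Rgs16, Slco1a1, Nat8f7, Rad51b and Igkv12-46 ended. With the clock component as a covariate, not centred by group, 200 of the 396 genes were shared, Ciart was at 1.04 and 10 lists were higher; with it centred by group 389 were shared (292 higher and 181 lower in all). With an estimated correlation 0 lists were called either way, and by fry 1 and 1. Of 40 named genes past the threshold 32 kept their call without each mouse in turn; Nat8f7 lost it without LD replicate 14, Rgs16 without LD replicate 18, and Fgf21, Ehhadh, Aurka, Slco1a1, Rad51b and Igkv12-46, all near the threshold, without several. Igkv12-46 was at 0.37 with DESeq2 and from -2.54 to 0.45 (without LD replicate 14) without single mice. Among genes that never passed, Chordc1 changed sign with voom (0.0039), S100a9 with the clock component (0.031), without the 3 libraries of largest mitochondrial share (0.022), LD replicate 13 (0.083) or 14 (0.14; -0.30 at the other end without single mice), Csf3r without LD replicate 14 (0.019; -0.13 at the other end), and Cfd with surrogate variables (-0.014). The 14 genes more variable in LD became 3 with squared deviations (Arntl, Dbp, Lgalsl), 6 with deviations from the median, 0 with the clock component regressed out, 50 (and 5 in ADV: Clpp, St6gal1, Zfp938, Pusl1 and Gm28177) with the mitochondrial share regressed out and 31 without the 3 libraries of largest share, and 8 to 39 without single mice. The whole-profile dispersion ranged from -7.38 (without ADV replicate 21) to -1.97 (without LD replicate 13). Correlations changed as follows without the 2 farthest mice, beside those within each side of the LD gaps, 3 of which changed sign (Arntl with Nr1d1 above 0.19, Arntl with Dbp below 0.034, Npas2 with Ciart above 0.16): Arntl with Nr1d1 in ADV 0.34, Per2 with Nr1d2 0.011 in ADV and 0.61 in LD, fibrosis with macrophage scores in ADV 0.30, macrophage with unfolded protein scores in ADV 0.034. With FPKM, Arntl with Nr1d1 over all LD mice went from -0.18 to 0.014, and Per2 with Nr1d2 was 0.014 in ADV and 0.53 in LD; lipogenesis with lipid droplet scores in ADV was -0.012 with hepatocyte scores regressed out. Except where construction is named, the cause was not tested. Depth limits genes near 1 CPM, such as Bhlhe41 and Aurka.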

Other observations

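Tests on fitted clock phase, on mitochondrial share and on LD replicate 13 were chosen after the clock values or spreads had been seen, except the association of other genes with phase within groups and the random splits of the mice. From 13 clock genes, the fitted phases of the LD mice had a circular mean of 5.56 h after lights on and lay within an arc of 11.7 h, longer than the sampling window of 8.5 h. They lay on both sides of a gap of 3.24 h, 8 from 23.7 to 2.36 h and 10 from 5.61 to 11.3 h, and 3 of 18 were within 2 h of the mean. Those of the ADV mice had a circular mean of 19.8 h and lay within 9.14 h, also longer than that window, with 8 of 23 within 2 h of the mean and 4 inside the LD arc. The mean resultant length was 0.415 in LD and 0.727 in ADV. Mice with neighbouring title numbers in a group had nearer phases than in drawn orders, with a mean gap of 1.99 h against a median of 4.27 h (one-sided permutation p = 1e-05, the smallest 100000 permutations can give). What the title numbers follow is not given in the labels. The fitted cosine accounted for a median share of 0.675 of the scaled values in LD and 0.712 in ADV. It accounted for only 0.287 and 0.240 in LD replicates 10 and 3, the mice at the edges of the gap in LD phases. The width of that gap is therefore uncertain. Per2 and Nr1d1 were among the 3 of these 13 genes with the larger SD in ADV.

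A hypothesis is that the clock genes differ because most ADV livers stood at other clock phases than LD livers when sampled. The mean fitted phases differed by -9.75 h (ADV minus LD; permutation p = 1e-05, the smallest 100000 permutations can give; -10.4 to -9.41 h leaving out any 1 gene), a difference between means near which few LD mice lay and which an advance and a long delay could both give. A difference in mitochondrial share is argued against, since the groups differed by -0.51 percentage points (two-sided permutation p = 0.467). All 7 called clock genes kept their call with that share as a covariate, but a covariate so alike in both groups could hardly end them. Whether RNA quality differed in other ways was not measured. Flatter rhythms in ADV cannot be told apart from a shift. The median SD ratio of ADV over LD, 0.693 (bootstrap 95% interval 0.483 to 0.806), lies between bounds that were set after the values had been seen. Such an SD also depends on how widely the phases of a group lie (arcs of 9.14 h in ADV and 11.7 h in LD). Fitted amplitudes were not compared between groups. Different sampling hours cannot be told apart either, because the arc of 19.2 h rests on assumed peak times, no hour per mouse is known, and neighbouring title numbers had near phases. A real difference between the light schedules stays open with these explanations.

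A second hypothesis is that called genes outside the clock list follow clock phase within the groups. Within groups, 49.1% of the 389 called genes outside that list were associated with fitted phase at an unadjusted p under 0.05, against 25.2% of the other genes. That excess of 23.9 percentage points was reached in 1 of 100 shufflings of phase within groups, the real order included (highest other 8.58). The shufflings remove the association from called and other genes alike (median excess 0.48). Called genes were not matched to the others for expression level or spread. The excess therefore cannot show that they follow phase more than comparable genes do. The association may come from anything that varies with phase between mice, such as the hour of sampling or feeding. Because neighbouring title numbers had near phases, which the shufflings broke, the order of sampling or processing could give it too, and none of these was separated.

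Most genes, 73.8%, had the larger SD in LD, a pattern that may come in part from RNA quality. Without LD replicate 13 the share was 56.9%, with the mitochondrial share regressed out within groups 50.9%, and without the 3 libraries of largest mitochondrial share 62.4%. The 14 genes that passed the spread test, 3 of them in the clock list, are another matter: 19 passed without LD replicate 13, and 0 with the clock component regressed out. With that component, which was built from the clock list, the median SD ratio of LD over ADV went from 3.79 to 2.20 for the 3 genes of that list and from 2.76 to 1.23 for the 11 others, and 3 of the 14 (Arntl, Dbp and Sgms1) kept a ratio over 2 at adjusted p = 0.416. A difference between the schedules in how far mice vary stays open for these 14 genes.

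Chance as the source of a total of 396 changed genes is argued against by random splits: 1 of 100 splits of the mice, the real one, gave as many, and the highest other gave 3. This bears on the total, not on single genes among the 396. The splits broke the order of title numbers, along which neighbours had near phases, so an effect of sampling or processing order is not excluded. For the 14 genes of different spread, 2 of 100 splits gave as many, the real one included, a count under the bound set beforehand for chance. The highest other split gave 280, so a random division of these mice can give far more genes, and chance is not excluded. What set that split apart was not identified. That split held the 3 libraries of largest mitochondrial share on its smaller side, as did 8 other splits, none of which gave any genes of different spread. Its count was 0 with the mitochondrial share regressed out within its sides and from 0 to 944 without single mice, checks chosen after seeing it. For the 9 called lists chance is not excluded, as 43 of 100 splits called as many and the highest other called 20.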
